A study of Mus musculus with 2 samples.

How the data were processed

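RNA was measured by strand-specific total RNA sequencing (Illumina TruSeq Stranded Total RNA libraries, HiSeq2500) in mouse trophoblast stem cells, the cultured stem cells of the placental lineage. The cells carried either a lentiviral short hairpin RNA against Prkci or a scrambled hairpin, and had been selected with puromycin. Per the labels' protocols, the lentivirus came from HEK 293T cells, a human kidney line widely used to package virus, and RNA was extracted on columns with a DNase step. The labels give 2 samples, 1 per group, named scramble and Prkci_knockdown. Nothing in the sources used here says how many libraries or cultures stand behind each group.

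The input was a single table of the authors' own comparison of knockdown with scramble. Per the submitters' processing notes, the tools named are bcl2fastq, STAR 2.5.2b, StringTie 1.3.0, HTSeq 0.6.1p1 and edgeR 3.12.1, with the mouse genome build GRCm38, and their roles and order are not stated. The table has 10588 rows for 10500 distinct loci, because 88 rows repeat a locus for another Entrez identifier, and each locus was used once. The authors' 2 expression columns are the mean counts per 1000000 (CPM) of each group, per their column names. Each of these deposited CPM columns sums to 1000000 over the 10500 loci, so the scaling was made over the loci kept in the table. The deposited log2 fold change and average log2 CPM come from the authors' fitted model. The log2 fold change lay 0.054 below the log2 ratio of the 2 means in the median locus, with quartiles of 0.059 and 0.048 below. The deposited score is a likelihood ratio statistic of the authors' test, and its chi-square tail with 1 degree of freedom equalled the deposited p-value at every locus to within rounding. The authors' adjusted p-value equalled the Benjamini-Hochberg adjustment of those p-values over the 10500 loci.

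No step that was tried made the means whole multiples of it. Steps were tried only from 0.1 times the lowest value of a group up to that value, so a finer step could have been missed. The best step made 22.9% of the low knockdown values and 21.5% of the low scramble values whole to within 0.1 of a read. Reads per library were therefore not recovered, the depth is unknown, and no counting interval was computed. The means have no spread of their own here, so no SD or n is attached to them.

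The log2 ratio of knockdown to scramble was computed as log2 of the ratio of the 2 means after adding a pseudocount of 0.5 CPM, which understates the change of low loci. The planned filter, a mean of at least 1 CPM, removed 0 loci because the lowest mean was 3.91 CPM. The design had been written for whichever unit arrived, and its branch for normalized values was used. With 1 labelled sample per group there is no replicate check, and no p-value was computed here between the groups. The p-values and adjusted p-values given are the authors'. They rest on a spread whose source is not stated, and 62.7% of loci had an unadjusted p above 0.5, more than an even spread of p-values would give. An approximate standard error of each log2 fold change was derived as its size divided by the square root of the deposited likelihood ratio score. On simulated counts of 3 against 3 libraries this approximation was 1.00 times the Wald standard error in the median of 2000 genes, with 0.994 and 1.02 at the 5th and 95th percentiles. The simulation used 1 known spread for all genes. Errors as large as some derived here, such as 1.33 for Vim, were not simulated. The words rose and fell are used only where the authors' adjusted p was below 0.05.

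A total of 32 gene lists with 820 symbols was fixed before the data were examined, and 521 of the symbols were listed in the table. For each list the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these values and is not a test between conditions. On simulated values for 10500 loci, 6 of 100 random lists fell outside the central 95%, and a list shifted by 0.4 reached the 100th percentile. The simulated values were independent across loci, so this checked the computation only, not lists of genes that vary together. The simulated shift was also larger than the highest list median found, 0.32. With errors of the approximate size drawn for the 10500 loci, 54% of loci changed 2.0-fold, 94% of those changed 3.0-fold and 98% of those changed 4.0-fold passed 2-fold, and 16% of those changed 1.5-fold did. Such errors alone would place 103 loci past 2-fold in each direction where 43 were higher, so they overstate the spread at least on that side and were not used as a no-change level. Beside each list stands the number of loci with an adjusted p below 0.05 when the authors' p-values were adjusted over the list alone.

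The rule for named genes was also fixed beforehand. It took Prkci, then the 10 largest rises and 10 largest falls in log2 ratio among loci with a mean of at least 5 CPM, leaving out predicted or clone names, small RNAs, ribosomal RNAs and mitochondrial genes. It added up to 4 members with the largest absolute log2 ratio from each list, and Gata2, Gcm1, Pparg, Cdx2, Eomes, Elf5, Esrrb, Prkcz, Pard6b and Pard3 whatever their values. Gcm1 had no row in the table used here. Gata2, Pparg and Gcm1 were included with knowledge of the later work on this gene, so their values are not independent evidence. Any other gene is named with the statement that it was chosen after its values were seen.

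Coordinates are the authors' on GRCm38. Annotation came from GENCODE vM21, on the same build, in which 10369 loci matched by Ensembl identifier. Of these, 4866 had the start and end of the annotated gene, and 8944 spanned the whole gene. Many loci are therefore wider than the gene they are named for, and other protein-coding genes with at least 0.5 of their length inside a named locus are stated. Where a symbol had more than 1 locus, as 30 symbols did, the locus with the higher mean was used. Alternatives covered the centring of the ratios, the pseudocount, the filter, the fold threshold, the loci counted, the matching of random lists and genes in more than 1 list. The authors' log2 fold change in place of the ratio, the counts without processed pseudogenes, without the X chromosome, without loci of over 2 times the approximate standard error usual at their level (the median of 20 bins of mean expression; also for the lists) or beyond 2 approximate standard errors, random lists without processed pseudogenes, and 2 changes to the authors' calls were added after the data were examined. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.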

Results

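Expression of 10500 loci was compared between mouse trophoblast stem cells carrying a hairpin against Prkci and cells carrying a scrambled hairpin. Prkci encodes atypical protein kinase C iota, a kinase of the apical polarity complex. The cells were kept under stem conditions, with fibroblast growth factor 4 and heparin in medium conditioned by embryonic fibroblasts. Each group is 1 labelled sample, and its values are the authors' mean read counts scaled to a common library total (counts per 1000000, CPM), with an unknown depth and an unknown number of libraries. There is no replicate check here on any difference.

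The first comparison asked whether the targeted transcript was reduced. Prkci (ENSMUSG00000037643, chromosome 3, 30995747 to 31052959, GRCm38, a protein-coding gene) had an authors' mean of 35.7 CPM in the knockdown and 121 CPM in scramble. The log2 ratio was -1.75, a 3.36-fold lower level. Prkci fell with the smallest adjusted p in the authors' deposited table, 8.48e-13, at a log2 fold change of -1.82 with an approximate standard error of 0.22. The direction fits the labels of both samples. Prkcz, the other atypical protein kinase C, had a log2 ratio of -0.51 and an adjusted p of 1.00 in the authors' deposited table, with an approximate standard error of 0.36.

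The second comparison asked which transcripts differed between knockdown and scramble. More loci were lower than higher in the knockdown: 371 of the 10500 loci were at least 2-fold lower and 43 at least 2-fold higher, around a median log2 ratio of 0.03. Loci that fell included Nrk, a kinase gene of the placenta, Wls, which encodes a Wnt carrier, Rhox9, a reproductive homeobox gene, and Cdkn1c, an imprinted inhibitor of the cell cycle. Few loci passed the authors' test. The authors' deposited table has an adjusted p below 0.05 at 28 loci, of which 26 fell and 2 rose in the knockdown. Processed pseudogenes, whose reads can be shared with their parent genes, made up 162 of the 371 lower loci; without them 209 were lower, without loci of any kind with over 2 times the approximate standard error usual at their level 225 were, and 164 of the 371 and 26 of the 43 lay beyond 2 approximate standard errors.

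**Figure D1:**
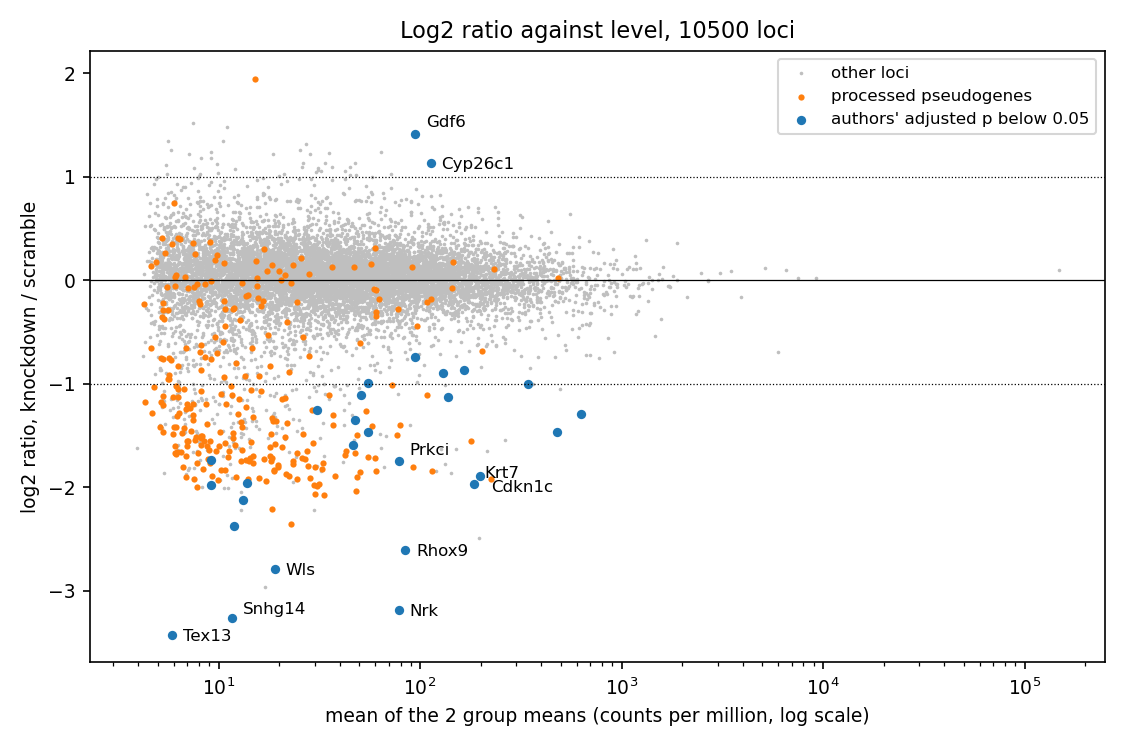
Log2 ratio of knockdown to scramble (vertical axis, pseudocount 0.5 CPM) against the mean of the authors' 2 group means (horizontal axis, CPM, log scale), 1 point per locus. Dotted lines mark 2-fold; processed pseudogenes (orange) lie mostly below the lower line, and the 28 loci with an authors' adjusted p below 0.05 (blue) include 26 lower and 2 higher loci.

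Of the 10 largest falls by the fixed rule, 6 passed the authors' test. Tex13 on the X chromosome was at 0.591 CPM in the knockdown against 11.2 in scramble, a 10.7-fold difference with the pseudocount of 0.5 CPM, against 20.4-fold and an adjusted p of 3.48e-07 in the authors' deposited table. A locus in the imprinted region of chromosome 7 (59937371 to 60140219) was 9.61-fold lower. It is named for the long non-coding RNA Snhg14, annotated at 59307924 to 59975759 and so overlapping it in part, and it also holds Snrpn, Snurf and Gm38393, so the value is not that of Snhg14 alone. Nrk (chromosome X, 138914392 to 139010532) fell from 141 to 15.1 CPM, with an adjusted p of 0.0020 in the authors' deposited table. Wls (chromosome 3, 159839672 to 159938664) fell from 33.8 to 4.47 CPM, with an adjusted p of 3.14e-11 in the authors' deposited table. Rhox9 and Arhgef6, both X-linked, fell to log2 ratios of -2.61 and -2.37. Of the X-linked protein-coding loci 36 of 299 were at least 2-fold lower, against 123 of 9517 autosomal ones. The imprinted RNA H19 was at 59.2 against 335 CPM, a log2 ratio of -2.49 that missed the threshold with an adjusted p of 0.071 in the authors' deposited table. Cdh5, the endothelial cadherin gene, had a log2 ratio of -2.21 and an adjusted p of 0.12 in the authors' deposited table. Rpl12-ps2, a processed pseudogene, and Pcdh7, a protocadherin gene, had ratios of -2.35 and -2.22 with approximate standard errors of 1.63 and 1.15. A set of 57 protein-coding loci had over 2 times the approximate standard error usual at their level and a median log2 ratio of -1.54. It includes Nrk, Rhox9, Pcdh7 and Cdh5, and H19 and Rpl12-ps2 had such errors too.

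Of the 10 largest rises only Gdf6, a growth factor of the bone morphogenetic family, passed the authors' test. Gdf6 (chromosome 4, 9844372 to 9862345) rose from 51.4 to 138 CPM, a log2 ratio of 1.42, with an adjusted p of 0.023 in the authors' deposited table. The others had higher levels that missed the threshold. Their log2 ratios were 1.52 for Slc43a3, 1.48 for Map1a, 1.34 for Fam19a5, 1.34 for Cdh4, 1.32 for Atp7b, 1.26 for Dkk3, 1.26 for Sox3, 1.24 for Dlgap1 and 1.24 for Dusp4. Sox3 is also among the 57 loci. Atp7b, a copper transporter gene, had the smallest adjusted p of these 9, at 0.26 in the authors' deposited table.

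The remaining loci past the authors' threshold were outside the rule and were chosen after their values were seen, apart from Prkci and the list members Cdkn1c, Dlg3 and Serpine1. The second rise was at the Cyp26c1 locus, which also holds Cyp26a1; both genes encode enzymes that break down retinoic acid, and the locus went from 70.4 to 155 CPM. Krt7, a simple epithelial keratin, fell from 295 to 75.1 CPM, with an adjusted p of 4.62e-08 in the authors' deposited table. Tfpi, which encodes an inhibitor of coagulation, fell from 706 to 255 CPM, and Cited2, a transcriptional co-regulator of placental development, fell from 69.6 to 32.1 CPM. Marcks, Bbx, Pramef12, Sept8, Csf1r, Fn1, Smarca2 and Anxa1 also fell, at log2 ratios from -0.74 for Sept8 to -2.12 for Anxa1. The ribosomal RNA locus Rn18s-rs5, the annotated microRNA locus Mir6236 and 3 loci without a symbol completed the 28.

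**Figure D2:**
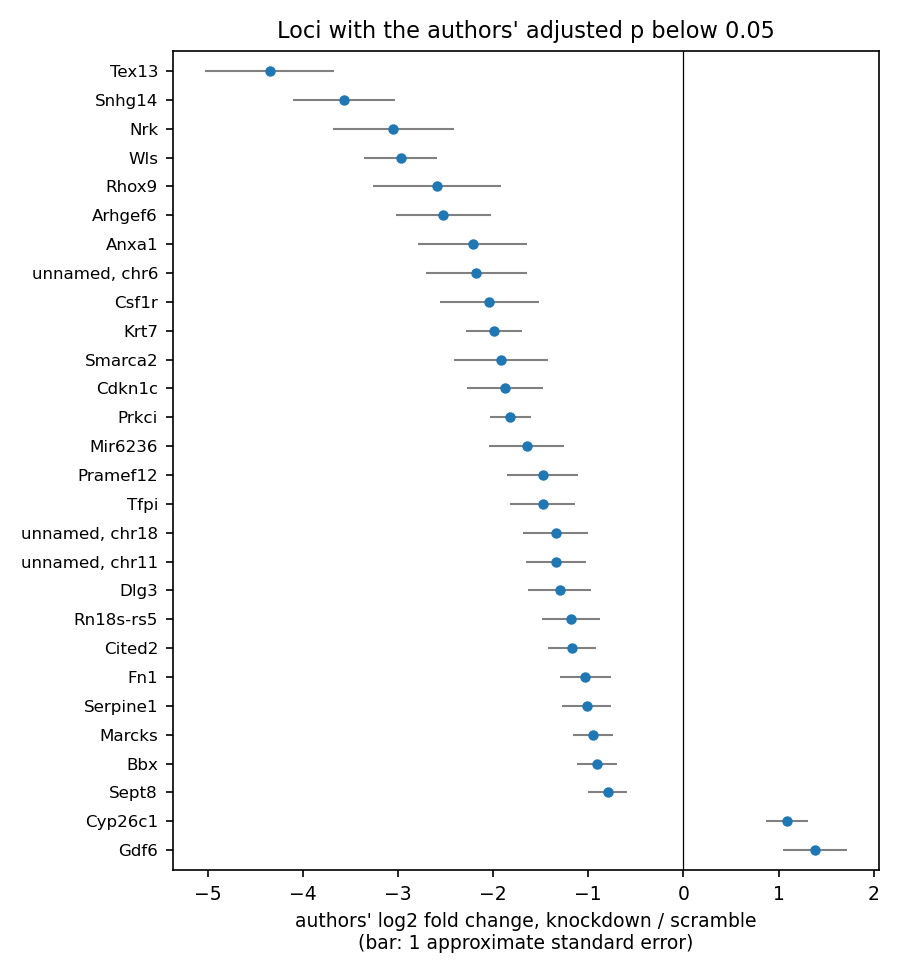
The authors' log2 fold change of knockdown against scramble (horizontal axis) for the 28 loci with an adjusted p below 0.05, 1 locus per line; bars are 1 approximate standard error derived from the authors' test statistic. Prkci stands at -1.82, and the 2 loci right of 0 are Cyp26c1 and Gdf6.

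Genes of the differentiated trophoblast types were lower in the knockdown, and those of the stem state were slightly higher. Every one of the 10 listed trophoblast giant cell loci had a ratio below 0, with a median log2 ratio of -0.64 at percentile 0 of the random lists. Among the members as listed, Nrk fell, and 5 loci were below 0.05 adjusted over the list alone. Both Nrk and Plac1 are X-linked, and X-linked protein-coding loci were at least 2-fold lower more often than autosomal ones. Plac1, Bhlhe40 and Serpinb9e had log2 ratios of -1.42, -1.26 and -1.06 without passing over all loci, and Serpinb9e belongs to a cluster of close paralogs that can share reads. Of 7 spongiotrophoblast and glycogen trophoblast loci, 6 were below 0, with a median of -0.45 at percentile 0.04. Cdkn1c fell from 314 to 84.5 CPM, with an adjusted p of 0.0028 in the authors' deposited table, and was the only locus past the threshold adjusted over the list alone. Phlda2 and Gjb3 had ratios of -0.92 and -0.53, and Pcdh12 had a ratio of 0.60. Nrk and Phlda2 are among the 57 loci with unusually large errors; without such loci the 2 medians were -0.61 and -0.45, at percentiles 0 and 0.05.

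The labyrinth progenitor and syncytiotrophoblast list had a smaller shift. Its 21 loci had a median log2 ratio of -0.10 at percentile 1.96, and 14 were below 0. None passed over all loci, and 4 were lower adjusted over the list alone. Those were Pparg, Gata2, Lgals3 and Met. Pparg, a nuclear receptor of the labyrinth lineage, was at 2.02 against 8.67 CPM, a log2 ratio of -1.86, with an adjusted p of 0.091 in the authors' deposited table. Gata2, a trophoblast transcription factor, was at 27.0 against 62.1 CPM, a log2 ratio of -1.19, with an adjusted p of 0.088 in the authors' deposited table. Lgals3, also among the 57 loci with unusually large errors, had a ratio of -1.62 and Met, the hepatocyte growth factor receptor gene, of -1.12. The list's median was -0.09 at percentile 1.98 without such loci. Pparg and Gata2 had been named with knowledge of later work on this gene and are not independent evidence.

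The 23 loci of trophoblast stem cell self-renewal had a median log2 ratio of 0.24 at percentile 100, with 18 above 0. No member passed over all loci, and Spry4 alone was below 0.05 adjusted over the list alone. Cdx2, Eomes, Elf5 and Esrrb, transcription factors of the stem state, had ratios of 0.57, 0.23, 0.36 and 0.36. The approximate standard errors of these 4 were 0.21, 0.23, 0.25 and 0.20. Duox2 had a ratio of 0.58, and Cdh3, which encodes placental cadherin, had a ratio of -0.84. Imprinted genes of placenta had a median of -0.08 at percentile 4.71 over 21 loci, and of 0.06 without the loci of unusually large error, H19 and Phlda2, or without genes in more than 1 list. Among them Cdkn1c fell, and H19 was lower adjusted over the list alone, as Mest, chosen after its values were seen, was higher. Dlk1 had a ratio of 0.98 with an approximate standard error of 0.90.

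Lists of cell polarity and contact had small negative medians with members on both sides of 0. The 23 loci of the apical-basal polarity complexes, a list that holds Prkci itself, had a median of -0.11 at percentile 0.43, with 15 below 0 and 8 above. Prkci and Dlg3, a scaffold gene on the X chromosome, fell, and no other member was below 0.05 adjusted over the list alone. Dlg3 had a log2 ratio of -1.25 with an adjusted p of 0.042 in the authors' deposited table. Inadl had a ratio of -0.52, Pard6b of -0.18 and Pard3 of 0.16. The 27 loci of the tight and adherens junction list had a median of -0.12 at percentile 0.22, with 19 below 0 and 8 above. The desmosome genes Dsc2, Dsg2 and Dsp were lower adjusted over the list alone, with ratios of -1.34, -1.15 and -0.74, and none passed over all loci. Pkp3, a further desmosome gene, had a ratio of -1.01. The 6 other protein kinase C isoforms had a median of -0.41 at percentile 0.42, with 4 below 0. Prkch was lower adjusted over the list alone at -1.30, Prkca had a ratio of -0.59 and Prkcb of 0.96. The Hippo pathway and YAP-TEAD targets had a median of 0.08 at percentile 84.7 over 22 loci. Amot, an X-linked angiomotin gene, was lower adjusted over the list alone at -1.02, and Tead2, F3 and Nuak2 had ratios of 0.62, 0.60 and 0.37.

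**Figure D3:**
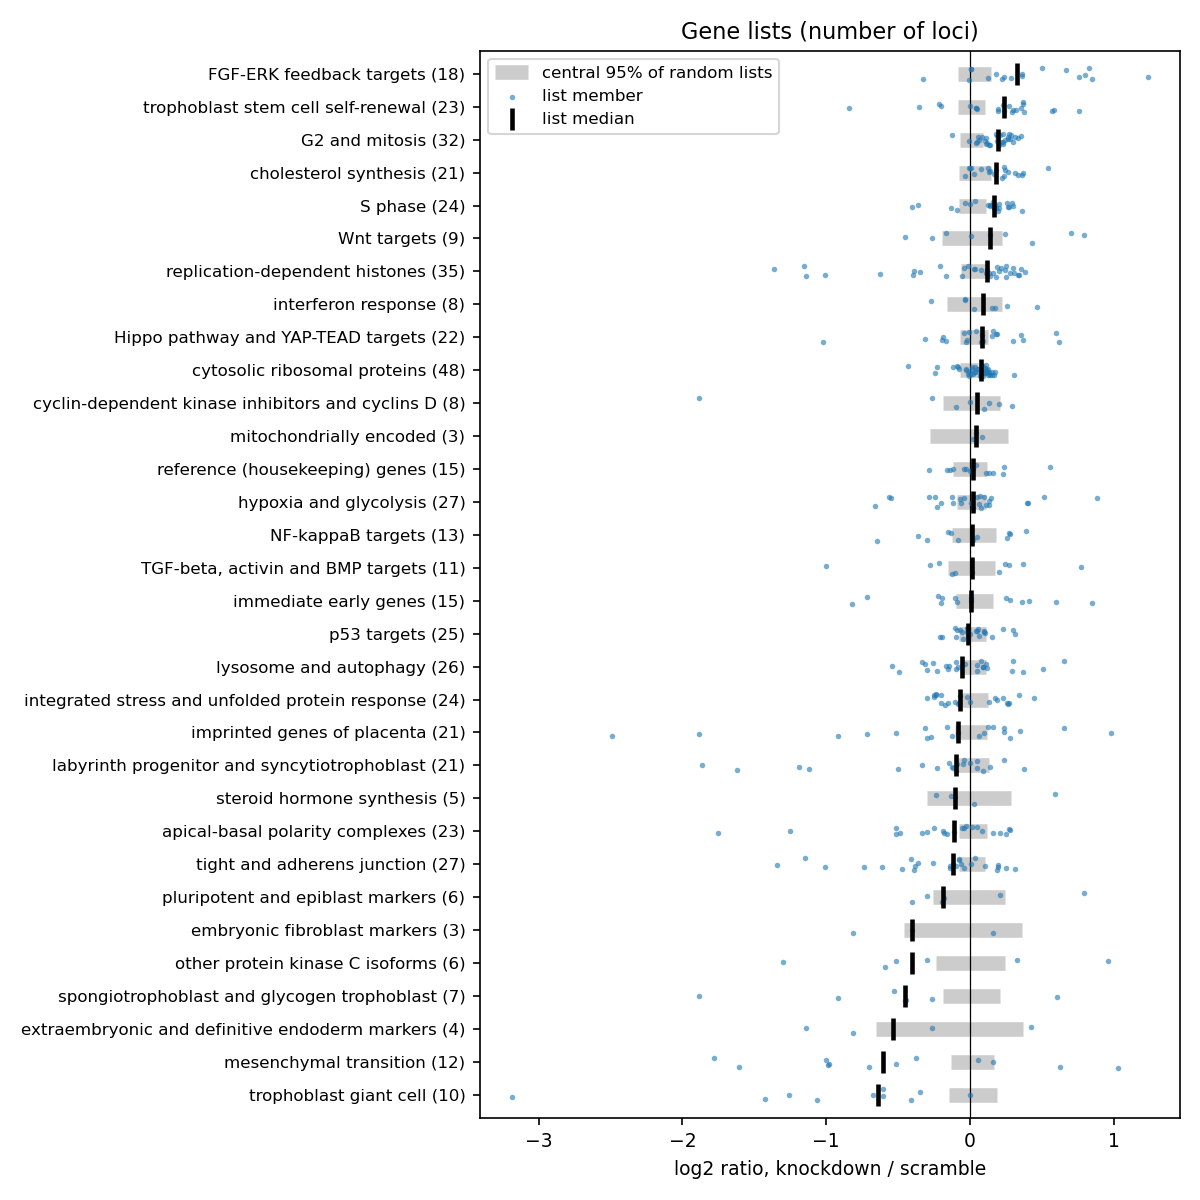
Log2 ratio of knockdown to scramble (horizontal axis) for the members of the 32 gene lists (points), with each list's median (black bar) and the central 95% of medians of 10000 random lists (grey). Lists stand in order of their median, from trophoblast giant cell at -0.64 to FGF-ERK feedback targets at 0.32.

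The mesenchymal transition list had a median of -0.61 at percentile 0.01 over 12 loci, 8 of them below 0. Serpine1, which encodes a plasminogen activator inhibitor, and Fn1, the fibronectin gene, fell, to 229 from 458 CPM and to 37.0 from 73.9 CPM, and 3 loci were lower adjusted over the list alone. Vim and Zeb2 had ratios of -1.78 and -1.61 with approximate standard errors of 1.33 and 0.81, and Zeb1 had a ratio of 1.03. Vim and Zeb1 are among the 57 loci with unusually large errors, and the median was -0.61 without them. The marker lists for other cell types that a culture could hold had few listed loci. Whether those loci were expressed by other cells or by the stem cells themselves was not tested. The embryonic fibroblast markers had 3 listed loci, a median of -0.40 and percentile 3.2, with Pdgfra, Col5a1 and Fbn1 at -0.81, -0.40 and 0.16. Without genes in more than 1 list their median was -0.12 at percentile 22.95. The percentile was 2.4 without loci of unusually large error and 2.2 against random lists without processed pseudogenes. The Fbn1 locus also holds Gm9913. The extraembryonic and definitive endoderm markers had a median of -0.54 at percentile 3.9 over 4 loci, with Cited1 at -1.14, Gata4 at 0.42 and Lama1 at -0.27. This median was -0.27 at percentile 13.4 without genes in more than 1 list. Against random lists without processed pseudogenes the endoderm list stood at percentile 1.6. The pluripotent and epiblast markers had a median of -0.19 at percentile 5.0 over 6 loci, with T, Tfcp2l1, Klf4 and Dppa4 at 0.79, -0.40, -0.30 and 0.21. No locus of these 3 lists was below 0.05 adjusted over the list alone.

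Feedback targets of fibroblast growth factor signalling were higher in the knockdown. The 18 FGF-ERK feedback loci had a median log2 ratio of 0.32 at percentile 100, and 16 were above 0. None passed over all loci, and Dusp4, Dusp6, Egr1 and Spry4 were higher adjusted over the list alone. Dusp6, a phosphatase gene induced by ERK, was at 161 against 90.6 CPM, Egr1 at 74.0 against 40.8 CPM and Spry4 at 113 against 66.8 CPM. Il17rd had a ratio of 0.80. Immediate early genes had a median of 0.01 at percentile 30.4 over 15 loci and 0 loci adjusted over the list alone, but without genes in more than 1 list their median was 0.25 at percentile 99.4, and the difference between the 2 lists was not tested. Jun and Klf6 had ratios of -0.82 and -0.71, against 0.60 for Maff. Wnt targets had a median of 0.14 at percentile 85.7 over 9 loci, with Apcdd1, Axin2 and Nkd1 at 0.70, -0.45 and 0.43. TGF-beta, activin and BMP targets had a median of 0.02 at percentile 46.7 over 11 loci. Serpine1 fell, and Id1, Smad7 and Pmepa1 had ratios of 0.77, 0.37 and -0.28. NF-kappaB targets had a median of 0.02 at percentile 37.9 over 13 loci, with Csf1, Nfkb1, Bcl3 and Nfkbiz at -0.65, 0.39, -0.36 and -0.30. The Nfkbiz locus also holds Nxpe3.

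Cell cycle lists had small positive medians. The 32 loci of G2 and mitosis had a median of 0.20 at percentile 100, with 30 above 0, and Nusap1, Cenpf, Ccnb1 and Bub1 at 0.35, 0.33, 0.31 and 0.30. The 24 S phase loci had a median of 0.16 at percentile 99.9, with Gins1 and Cdc45 at 0.36 and 0.30 and Pola1 and Ccne2 at -0.40 and -0.36. No locus of either list passed, also adjusted over the list alone. The 35 replication-dependent histone loci had a median of 0.12 at percentile 98.7 and 0 loci adjusted over the list alone. Hist1h1b, Hist1h4k and Hist2h3c2 had ratios of -1.37, -1.16 and -1.14. Hist1h2br had a ratio of -1.01, and its locus of 118 kb holds 14 other histone genes, Hist1h1b and Hist1h4k on the opposite strand among them. Whether these loci share reads was not tested. Of 8 cyclin-dependent kinase inhibitors and cyclins D, Cdkn1c fell, and the median was 0.05 at percentile 59.1. Cdkn2d, Ccnd1 and Cdkn2b had ratios of 0.29, -0.26 and 0.20.

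Of the metabolic and stress lists, only cholesterol synthesis lay outside the central 95% of random lists at the main settings. The 21 cholesterol synthesis loci had a median of 0.18 at percentile 99.6, with 19 above 0 and Idi1, Sqle, Pmvk and Dhcr7 at 0.54, 0.37, 0.36 and 0.33. Steroid hormone synthesis had a median of -0.10 at percentile 16.0 over 5 loci, with Srd5a1 at 0.59, Stard3 at -0.24, Fdx1 at -0.13 and Fdxr, whose locus also holds Fads6, at -0.10. Hypoxia and glycolysis had a median of 0.02 at percentile 59.4 over 27 loci. Pdk1 was higher adjusted over the list alone at 0.88, and Ndrg1, Aldoc and Vegfa had ratios of -0.66, -0.56 and -0.55. The integrated stress and unfolded protein response had a median of -0.07 at percentile 3.8 over 24 loci, with Mthfd2, Slc3a2, Phgdh and Psat1 at 0.45, 0.34, -0.30 and 0.27. Lysosome and autophagy had a median of -0.06 at percentile 4.2 over 26 loci, with Naglu, Ctsl, Gabarapl1 and Lamp2 at 0.65, -0.54, 0.51 and -0.49. The p53 targets had a median of -0.01 at percentile 25.9 over 25 loci, with Zmat3, Pmaip1, Ddit4 and Ei24 at 0.31, 0.30, 0.23 and -0.21. Interferon response had a median of 0.09 at percentile 67.8 over 8 loci, with Parp14, Eif2ak2, Bst2 and Ifi35 at 0.47, -0.27, 0.26 and 0.18. Apart from Pdk1, no locus of these 7 lists was below 0.05 adjusted over the list alone.

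Reference and core genes had medians near 0, though the cytosolic ribosomal proteins lay outside the central 95% of random lists. The 15 reference (housekeeping) loci had a median of 0.02 at percentile 64.0, with B2m, Pgk1, Tfrc and Gusb at 0.55, -0.29, 0.23 and 0.23. The 48 cytosolic ribosomal protein loci had a median of 0.08 at percentile 99.7 with Rpl11, Rpl18a, Rps4x and Rps18 at -0.43, 0.31, -0.24 and -0.23. The mean log2 ratio had the opposite sign to the median in 6 lists. It was 0.02 for p53 targets, -0.03 for NF-kappaB targets, -0.19 for the cyclin-dependent kinase inhibitors and cyclins D, -0.0027 for hypoxia and glycolysis, 0.03 for steroid hormone synthesis and -0.07 for replication-dependent histones. The 3 mitochondrially encoded loci had a median of 0.04 at percentile 63.5. Of these, mt-Nd6 and mt-Cytb had ratios of 0.08 and 0.04, and mt-Co1, whose locus holds 8 other coding genes, had a ratio of 0.02. No locus of these 3 lists was below 0.05 adjusted over the list alone.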

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

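Tests and counts without the processed pseudogenes, without the X chromosome, without loci of over 2 times the usual standard error, beyond 2 approximate standard errors, with the authors' log2 fold change or with other thresholds on the authors' adjusted p were chosen after the data were seen. The log2 ratio of Prkci ranged from -1.82 to -1.74 over the alternatives. At a 1.5-fold threshold 262 loci were higher and 630 lower, and at 4-fold 0 were higher and 19 lower. Counting only symbols that are not predicted or clone names left 186 lower loci, leaving out processed pseudogenes left 209, and leaving out loci with over 2 times the usual standard error left 225. Beyond 2 approximate standard errors stood 26 higher and 164 lower loci. These changes follow from which loci were counted. With the authors' adjusted p below 0.1 in place of 0.05, 51 loci passed. Centring the ratios, either pseudocount, the stricter filter, the authors' log2 fold change and leaving out the X chromosome kept both counts within 1.5 times. A total of 14 lists lay outside the central 95% of random lists, and between 14 and 16 did over the alternatives. With the authors' log2 fold change 7 list medians near 0 changed sign, centring changed 5, and leaving out loci of over 2 times the usual error or genes in more than 1 list changed 1 each, imprinted genes of placenta. The lists that crossed were imprinted genes of placenta, lysosome and autophagy, immediate early genes, embryonic fibroblast markers and the endoderm markers. Of 1075 values for named genes under an alternative, 1 moved by more than its approximate standard error, Tex13 at -4.35 in the authors' deposited table. Of 288 list medians under an alternative, 15 moved by more than the bootstrap SD of that list's median. The as-deposited scaling and the absence of a filter equal the values reported, and no counts were used, so the choice between counts and a normalized unit was not run. No paired analysis was possible because each group is 1 labelled sample. The unknown depth limits every value.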

Other observations

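All tests in this part were chosen after the values were seen. Gene families, of which Serpinb9e and Rhox5 also stand in the fixed lists, were looked at without a comparison with random lists. Their only members past the authors' threshold were Krt7 and Rhox9, both reported above. All 5 listed keratin loci had ratios below 0: Krt8 was at 325 against 671 CPM and Krt18 at 706 against 1137 CPM, beside Krt7 at 75.1 against 295 CPM. Krt19 and Krt10 had ratios of -0.75 and -0.07, with approximate standard errors of 0.55 and 0.52, so Krt10 was almost level. The simple epithelial keratins Krt8 and Krt18 had adjusted p-values of 0.24 and 0.14 in the authors' deposited table and so did not pass. All 5 Serpinb9 family loci, a cluster of close paralogs on chromosome 13 that can share reads, were at least 2-fold lower, with a median log2 ratio of -1.23 and none past the authors' threshold. The X-linked Rhox family split, with Rhox9 at -2.61 and Rhox6 at -1.86 but Rhox5 at 0.36 and Rhox4g at 0.12.

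Processed pseudogenes were lower in the knockdown, with a median log2 ratio of -1.23 over 270 loci (bootstrap SD 0.071) and approximate standard errors 1.64 times those usual at their level. A fall of the parent genes is argued against by 35 named pairs. Their pseudogene minus parent difference had a median of -1.19 (bootstrap SD 0.26), while the parents had a median of 0.06. The differences ran from -2.47 for Rpl12-ps2 to 0.39 for Mrto4-ps2, and some pairs, such as Rps26-ps1 at 0.04, had almost none. The argument covers only pairs whose pseudogene was lower than its parent. Some parents, such as Rpl19, stand in more than 1 pair, so the pairs are not independent. For genomic DNA in scramble, 983 low protein-coding loci had a median excess of -0.070 CPM per kilobase, against 9.25 CPM per kilobase for the pseudogenes (SD 1.46). These coding loci were picked for a low level, with a highest mean of 8.84 CPM, which caps the excess they could have. The comparison therefore does not decide on genomic DNA. It replaced a first test whose outcome mappability could set. RNA of another cell type or organism in some scramble libraries stays open as a candidate source. The 57 protein-coding loci with over 2 times the usual standard error, picked without regard to direction, had a median of -1.54. Of them 45 were below 0 and 34 were at least 2-fold lower. The other protein-coding loci had a median of 0.04, so the 57 were lower as a set. Past 2-fold, lower loci also outnumbered higher ones among all protein-coding loci, the 57 included, with 159 at least 2-fold lower and 38 at least 2-fold higher. The direction of the 57 does not by itself single out such a source. Among the 57 stand Hoxa5, Hoxa9, Hoxb6, Hoxb9 (with Hoxb7 and Hoxb8), Hoxd11 (with Hoxd10) and Vim at ratios from -1.64 to -1.99. Nrk, Rhox9, Cdh5, Pcdh7, Lgals3, Phlda2 and Krt19 are also among them, so the open source could cover these as well. A real effect of the knockdown on the 57 loci was not tested.

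X-linked protein-coding loci were lower more often than autosomal ones, with 12.0% of 299 loci at least 2-fold lower against 1.29%. Loss or silencing of a whole X in some cells is argued against as the whole cause, because the shift against the autosomes was -0.86 at the 10th percentile and -0.08 at the 75th, a difference of -0.78 (bootstrap SD 0.11). The source behind the pseudogenes stays open: 15 X loci, Nrk, Rhox9 and Rhox6 among them, had over 2 times the usual standard error, and 12 of these were at least 2-fold lower. Among loci under 1.19 times the usual error, where 0 of 89 pseudogenes were at least 2-fold lower, 3.10% of 226 X loci were, against 0.41% of autosomal loci (bootstrap SD of the difference 1.12), but among loci below the usual error 1 of 116 X loci was (0.86%), against 0.041% of autosomal loci, an excess of 0.82 percentage points in the same direction but within its bootstrap SD of 0.84, so the test, whose limits were set after the values were known, does not decide. An effect of the knockdown on X-linked genes of usual error, such as Arhgef6, Dlg3 and Amot, stays open too and was not tested further.

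Protein-coding loci of chromosome 13 were shifted up by 0.11 on the log2 scale against the other autosomes (388 loci, bootstrap SD 0.010), the largest shift of the 19 autosomes, and chromosome 3 was shifted by -0.09. Genes of a chromosome are not independent replicates, and a bootstrap SD over genes does not measure the spread among chromosomes. The next largest upward shift was 0.07, of chromosome 18. A bias by GC content, transcript length or level is argued against, since the shift was 0.12 (bootstrap SD 0.011) after those trends were removed. A gain of chromosome 13 in some knockdown cells may account for it, and would need about 15.8% of cells with 1 extra copy. Its test, as reworded, does not decide. The shift was above 0 at 5 of 5 quantiles and in 6 of 6 windows of 20 megabases, but the smallest quantile shift was 0.072 (bootstrap SD 0.045). The criterion for this test was reworded after its value was known. By the first wording the gain failed, because the smallest shift was too small for its bootstrap SD.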
